A study of Drosophila melanogaster with 18 samples.

How the data were processed

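Total RNA from 18 samples of Drosophila melanogaster DL1 cells was depleted of ribosomal RNA and sequenced as strand-specific libraries, per the labels' protocols. Parental DL1 cells and stable puromycin-selected DL1 populations carrying a FLAG-tagged IntS6 or IntS12 transgene behind the copper-inducible MtnA promoter were grown for 3 d at 25 °C. In 3 samples of each kind of cell 500 µM copper sulfate was present for the last 24 h. This gave 6 groups of 3 libraries, with the group and the replicate letter (A, B or C) taken from each sample's title. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

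The deposited table holds, for 17753 FlyBase gene identifiers, the authors' counts per gene in each library, which are estimated counts because 13.4% of the values were not whole. Of the non-whole values, 90.7% ended, after rounding to 2 decimals, in the fractions that sharing a read among 2, 3, 4 or 6 places gives. Reads were trimmed with Trimmomatic 0.39 and counted with featureCounts on dm6/BDGP6, per the submitters' processing notes. The aligner, the annotation release, the strand setting and the other counting options are not given in the sources used here. All table columns matched a sample by the library name in its description. A symbol was found for 17626 identifiers in a table of FlyBase gene names, and 127 had none. Coordinates, gene lengths and overlaps came from the BDGP6.54 gene annotation.

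Counts were rounded to whole numbers and tested in R 4.3.3. Library totals ran from 13217764 to 18214756 counts. Genes whose symbol names an rRNA held 70.2% to 73.4% of each library, which left 3.69 to 4.94 M other counts per library, and these genes were kept in library sizes and tests. All 18 libraries entered 1 edgeR 4.0.16 fit with 6 group means, TMM factors and the default filter on low counts, which kept 8174 of the 13350 genes with any count. The quasi-likelihood F-test had 12 residual degrees of freedom per gene and a prior of 9.62, and the biological coefficient of variation was 8.0%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each of 10 comparisons: each transgene line against parental cells with and without copper, each kind of cell with against without copper, the copper-treated lines against each other, and for each line its copper response minus that of parental cells. CPM values used TMM-scaled library sizes, and every ± beside a log2 fold change is a standard error with 3 libraries per group, taken as the size of the log2 fold change divided by the square root of its F statistic. Against a group with 0 counts, fold changes were computed as lower bounds with a floor of 3 counts over the group. With 1 to 3 counts in the lower group, the ratio of summed counts is given with its exact 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

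The text names genes by a rule fixed before the data were examined. It covers IntS6 and IntS12 everywhere and, in the comparisons of each copper-treated line with copper-treated parental cells and of copper in parental cells, the 8 genes per direction with the largest fold changes among called genes with non-overlapping CPM and a mean of at least 5 CPM in the higher group. In other comparisons it takes 3 per direction, and in each described gene list up to 4 members with the smallest p. Genes named outside this rule are said to be so. Further overlaps with other annotated features covered exon bases of Ets21C (28.3%), Atf6 (19.8%), RpL37A (19.7%) and Treh (12.8%) on the other strand and of Sesn (65.1%) on the same strand. The values of 1 gene that the rule names are not reported here. In the same step 24 gene lists were fixed, of which the fat body list had 0 tested members and 23 were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. Each list was repeated with an estimated correlation and with fry. Lists share some members, among them peb, kay, Pepck1, MtnA, MtnB and MtnD, so they are not independent of each other. List symbols without a match were mtsl, Nelf-B, Hsp67Bb, Prx2540-1, Prx2540-2, nazo, Eip71CD and nos. Replication-dependent histone genes and the 6 Hsp70 genes are near-identical copies whose reads the counting could split, so their counts were also summed per family and tested as 1 gene. Counts of list members and list tests keep these copies as separate members.

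Replicates were compared first: no pair within a group agreed within counting noise, and none were merged. The letters A, B and C were examined as a possible pairing. Deviations from the group mean correlated above 0.1 for every same-letter pair in 2 comparisons, IntS6 with copper against parental cells with copper (0.21, 0.24 and 0.13) and parental cells with against without copper (0.12, 0.11 and 0.28), so a fit with the letter as a block was compared for these. Alternatives were RLE size factors from edgeR, library sizes alone, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate block, only the groups compared, DESeq2 1.42.0, an adjusted p under 0.001 with a fold over 1.5, and each library left out in turn. Leaving out the rRNA genes was added after the data were seen.

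The fold changes of the IntS6 and IntS12 lines against the same 3 parental copper libraries share those libraries' error. Their correlation and covariance were therefore set beside those of 20 simulations in which all copper libraries, controls included, were drawn from 1 mean per gene. Tests were tried on simulated data before use. With 200 genes changed in the comparison of IntS6 with parental cells, both with copper, edgeR on 8174 genes made 172 calls, of which 10 were false. It recovered 56.7% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold. With 0 genes changed in the comparison of IntS12 with parental cells, both with copper, edgeR made 0 calls among 8174 genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.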

Results

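Gene expression was measured in DL1 cells, a cultured Drosophila cell line, that overexpressed a subunit of Integrator, an RNA polymerase II-associated complex that cleaves nascent transcripts and attenuates transcription of some protein-coding genes. IntS6 and IntS12 are subunits of this complex. Each of the 6 groups held 3 libraries: parental cells, the IntS6 line and the IntS12 line, each without copper or after 24 h in 500 µM copper sulfate. Total counts per library ran from 13217764 to 18214756, of which 3.69 to 4.94 M lay outside rRNA genes. In a principal component analysis the first component (61.5% of the variance) separated libraries with copper from those without. On the second (8.4%) the 3 IntS6 libraries with copper lay at -21.3 to -16.8 and the other copper libraries at 8.2 to 17.4.

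IntS6 (FBgn0261383, chromosome X of BDGP6.54, 5738663 to 5747254, minus strand, protein-coding) reached 2370 ± 174 CPM (SD, n = 3) in the IntS6 line with copper, against 36.3 ± 1.45 CPM in parental cells with copper and 71.4 ± 3.58 CPM in its own line without copper. In the other groups IntS6 stood at 28.0 ± 1.51 CPM in parental cells without copper and at 31.3 ± 0.581 and 40.5 ± 3.39 CPM in the IntS12 line without and with copper. This was a 65.1-fold rise over copper-treated parental cells (log2 fold change 6.02 ± 0.08, edgeR adjusted p = 2.15e-23). IntS12 (FBgn0039459, chromosome 3R, 26863376 to 26864559, plus strand, protein-coding) reached 92.9 ± 3.92 CPM in the IntS12 line with copper against 3.62 ± 0.317 CPM in copper-treated parental cells, a 25.6-fold rise (log2 4.68 ± 0.12, adjusted p = 1.1e-17). It stood at 8.44 ± 1.29 CPM in its own line without copper, 4.98 ± 0.512 CPM in parental cells without copper, and 4.22 ± 0.374 and 3.30 ± 0.682 CPM in the IntS6 line without and with copper. Each transgene was thus highest in the line and treatment its label names. Induced IntS6 had more CPM than induced IntS12, but CPM are not scaled for gene length, so numbers of transcripts were not compared. Without copper IntS6 was already 2.55-fold higher in its line than in parental cells (adjusted p = 1.31e-10). IntS12 was 1.68-fold higher in its line without copper (adjusted p = 0.0366). That call ended when only the 2 groups compared were fitted (adjusted p = 0.23) and without parental library A (0.068), B (0.133) or C (0.165) or IntS12 library B (0.303) or C (0.269). Copper itself raised IntS6 1.3-fold in parental cells (adjusted p = 0.000524) and lowered IntS12 by 1.38-fold (adjusted p = 0.0217). The fall of IntS12 was not called when only these 2 groups were fitted (0.0596) or without parental library A (0.0929) or parental copper library B (0.0723) or C (0.0599). Counts per gene do not separate transgene from endogenous transcripts.

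**Figure D1:**
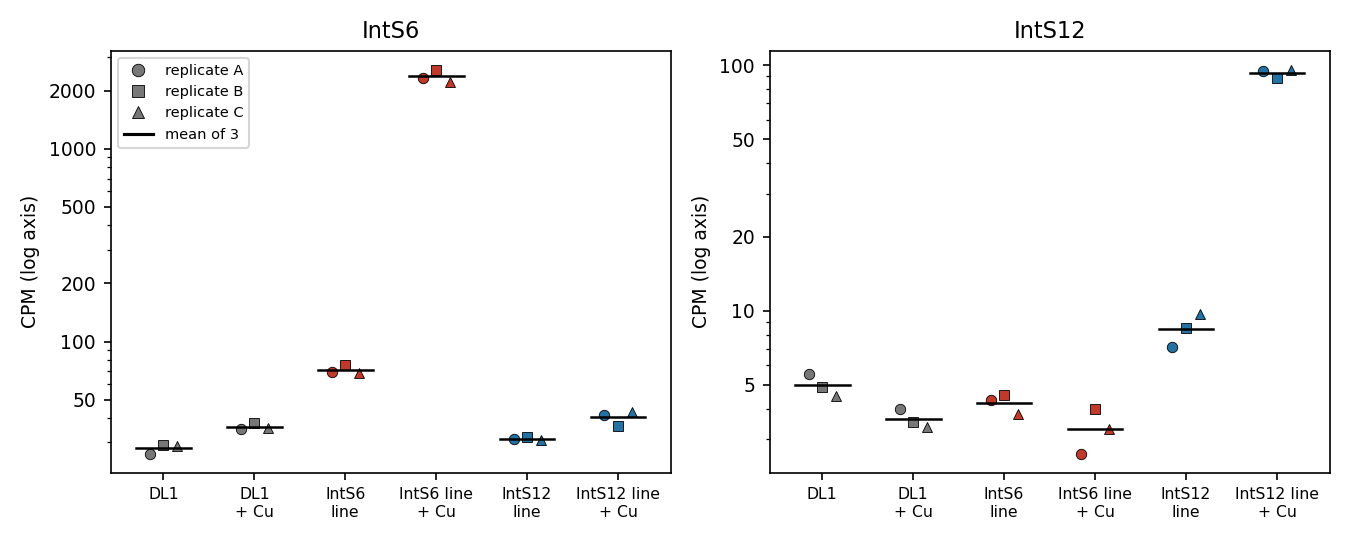
CPM of IntS6 and IntS12 on a log axis in each of the 18 libraries, by group, with symbols for the replicate letters and a line at the mean of 3. IntS6 stands at a mean of 2370 CPM in its line with copper and IntS12 at 92.9 CPM in its own.

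Copper alone was examined first, as the background of every induced sample. In parental cells it raised the metallothioneins, small copper- and zinc-binding proteins: MtnA rose 112-fold (log2 6.80 ± 0.19, adjusted p = 1.12e-16) and MtnE 164-fold (log2 7.36 ± 0.36, and 8.00 without parental library B). MtnD and MtnB had 0 counts in the untreated parental libraries and were at least 274-fold and at least 74.9-fold higher. ChLD3, a predicted chitin deacetylase gene, rose with a ratio of counts of 83.5 (interval 28.2 to 407, from 3 counts without copper). Its fitted log2 fold change of 6.17 was 9.37 without parental library C and 5.57 without parental copper library B. Other genes with large rises were NtR (20.4-fold), CG43968 (18.8-fold), the kinase gene sff (17.1-fold, log2 4.09, and 4.85 without parental library A) and CG8046 (16.3-fold). The largest falls among named genes were those of CG6675 (6.63-fold), the mucin gene Muc14A (3.49-fold), the glycosyltransferase gene Pgant9 (3.45-fold), CG12698 (3.3-fold), tutl (3.29-fold), the lipocalin-like Karl (3.23-fold) and the linker histone copies His1:CG33816 (3.13-fold) and His1:CG33822 (2.88-fold). In all 1577 genes rose and 1582 fell, 3159 of 8174 tested. ChLD3 and Karl overlap antisense genes over 13.1% and 24.2% of their exon bases, and whether the counting used strand is not given in the sources used here.

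Of 12 measured genes for metallothioneins and copper or zinc handling, 10 rose with copper in parental cells, and 10 did so adjusted over the list alone. Their median log2 fold change was 0.57, also with the genes at 0 set to their bounds (camera adjusted p = 4.37e-08, and adjusted p = 0.0207 with an estimated correlation). Among 26 genes of oxidative stress and glutathione metabolism 21 rose and 1 fell, with the same counts adjusted over the list alone. They included Gclc, which encodes the catalytic subunit of glutamate-cysteine ligase (2.88-fold), and the glutathione transferase genes GstE6 (3.98-fold), GstD1 (3.28-fold) and GstE8 (4.44-fold), with a camera adjusted p = 6.26e-10 and adjusted p = 0.0318 with an estimated correlation. Of 8 genes described earlier as attenuated by Integrator, 5 rose and 1 fell, counts that stayed at 5 and 1 adjusted over the list alone. MtnA, MtnB and MtnD were among those that rose, and pst rose 2.21-fold (camera adjusted p = 0.000126, and adjusted p = 0.0279 with an estimated correlation).

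Replication-dependent histones fell together with copper: 108 of 111 genes were lower, and 111 adjusted over the list alone, with the summed His1 copies down 2.7-fold (355 to 132 CPM) and the other summed classes down between 1.55-fold for His2B and 1.74-fold for His4. Their camera adjusted p was 5.68e-22, and adjusted p = 0.351 with an estimated correlation. These copies are near-identical, so single copies are uncertain. Of 32 DNA replication and cell cycle genes 22 fell and 0 rose (23 and 1 adjusted over the list alone), among them the mitotic kinase gene polo (2.12-fold), CycB (1.88-fold), Cdk4 (1.58-fold) and stg, the Cdc25 phosphatase gene (1.49-fold). That list had a camera adjusted p = 9.51e-07, and adjusted p = 0.351 with an estimated correlation. Ribosomal protein genes fell in 36 of 82 cases, and adjusted over the list alone 42 fell and 1 rose, by small amounts (RpL37A 1.24-fold, RpL9 1.3-fold), with a camera adjusted p = 4.8e-06 and adjusted p = 0.526 with an estimated correlation.

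Glycolysis and gluconeogenesis genes rose in 12 of 14 cases, and 13 adjusted over the list alone, among them Ldh (3.94-fold), Pfk (2.01-fold), Gapdh2 (1.6-fold) and Hex-A (1.42-fold), with a camera adjusted p = 3.94e-05 and adjusted p = 0.351 with an estimated correlation. Of 18 heat shock genes 11 rose (12 adjusted over the list alone), led by the stress-induced noncoding RNA lncRNA:Hsromega (6.25-fold) and Hsp22 (7.19-fold, all of whose exon bases are shared with CG4456). That list had a camera adjusted p = 0.000143 and adjusted p = 0.351 with an estimated correlation. ATF4 and amino acid starvation genes rose in 9 and fell in 2 of 16 cases (10 and 2 adjusted over the list alone), with Sesn up 3.08-fold and Cbs 1.57-fold (camera adjusted p = 0.0124, and adjusted p = 0.214 with an estimated correlation). Sterol and fatty acid synthesis genes rose in 8 and fell in 2 of 16 cases, as they did adjusted over the list alone, with Hmgs up 2.47-fold (camera adjusted p = 0.0415, and adjusted p = 0.526 with an estimated correlation). The sterol call ended with the replicate block (adjusted p = 0.0504). Pausing and elongation factor genes fell in 5 of 15 cases, also adjusted over the list alone, among them Hexim (1.45-fold), with a camera adjusted p = 0.0292 and adjusted p = 0.119 with an estimated correlation. The JNK and JAK-STAT list did not pass (camera adjusted p = 0.0716), though 8 of its 17 members rose and 4 fell, with Mmp2 up 9.78-fold and egr, the fly TNF ligand gene, up 7.68-fold. Sesn shares 65.1% of its exon bases with another gene on the same strand.

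Overexpression of IntS6 was followed against parental cells given the same copper. Hml (FBgn0029167, chromosome 3L, 13846054 to 13860001, plus strand), which encodes the large clotting protein hemolectin of plasmatocytes, rose 11.7-fold (log2 3.55 ± 0.31, n = 3 per group, adjusted p = 1.12e-07). Liprin-gamma rose 7.67-fold (log2 2.94 ± 0.32), the ABC transporter gene Mdr49 7.51-fold (2.91 ± 0.20), the microtubule-associated protein gene futsch 6.38-fold (2.67 ± 0.17), the glutamine synthetase gene Gs2 6.3-fold (2.66 ± 0.26) and ringer 5.43-fold (2.44 ± 0.22). The atypical cadherin gene ds was 6.52-fold higher (2.71 ± 0.37, and 3.47 without parental copper library C), but it was already 5.58-fold higher in this line without copper. Likewise ringer already stood at 2.03 ± 0.371 CPM in this line without copper, against 0.56 ± 0.109 CPM in parental cells without copper (SD, n = 3). Among genes called lower, lncRNA:Hsromega was 2.05-fold lower, CROT, a carnitine acyltransferase gene, 1.76-fold, and wde, which encodes a cofactor of histone H3 lysine methylation, 1.53-fold. In this line copper raised lncRNA:Hsromega from 53 to 156 CPM and wde from 11.5 to 21.8 CPM, less than in parental cells (51.1 to 319 and 11.1 to 33.4 CPM). CROT stood at 4.43 and 4.38 CPM in this line without and with copper, and at 4.12 and 7.72 CPM in parental cells. In the IntS12 line with copper lncRNA:Hsromega, wde and CROT lay between the 2 levels, at 215, 29.3 and 6.22 CPM. None of them was called there against parental cells. Parental copper libraries A, B and C held 365.6, 360.5 and 231.3 CPM of lncRNA:Hsromega. CG9752 (1.72-fold lower), Dnah3 (1.71-fold), CG10194 (1.55-fold), Rim (1.53-fold) and lncRNA:CR45334 (1.53-fold) were also called lower. Tmtc2, outside the rule for named genes and chosen after its values were seen, had a log2 fold change of -3.16 (adjusted p = 7.31e-06). It was already lower in this line than in parental cells without copper, with values given further below, so the difference was present before induction.

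In all 728 genes changed with IntS6, 609 higher and 119 lower, and 225 rose while 3 fell by more than 2-fold. No spike-in counts were used, so these directions are relative to the other transcripts of each library and a global change in RNA per cell cannot be seen. When only the groups compared were fitted 454 were called, 410 higher and 44 lower. With library sizes alone 686 were higher and 51 lower, without a filter on low counts 694 and 210, without IntS6 copper library A 450 and 71 or C 478 and 66, and without parental copper library B 617 and 195. For several named genes called lower the call was lost in more than 1 way, while the log2 fold change in those fits stayed negative: -0.64 to -0.80 for CG9752 against -0.78, -0.45 to -0.67 for Rim against -0.62 and -0.52 to -0.64 for CG10194 against -0.63. CG9752 lost its call without parental copper library A or C (adjusted p = 0.0875 and 0.133), without IntS6 copper library B or C (0.117 and 0.101) and when only the groups compared were fitted (0.0624). Dnah3 lost it with DESeq2 (0.106), without parental copper library C (0.241) and without IntS6 copper library A or B (0.167 and 0.136). CG10194 lost it when only the groups compared were fitted (0.0611) and without parental copper library C (0.062) or IntS6 copper library C (0.0568). Rim lost it when only those groups were fitted (0.0705) and without parental copper library C (0.175) or IntS6 copper library A or B (0.0612 and 0.145). lncRNA:CR45334 lost it with DESeq2 (0.0602), with library sizes alone (0.0639), when only those groups were fitted (0.0662). It also lost it without parental copper library A or B (0.0548 and 0.187) or IntS6 copper library A or C (0.0763 and 0.188).

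**Figure D2:**
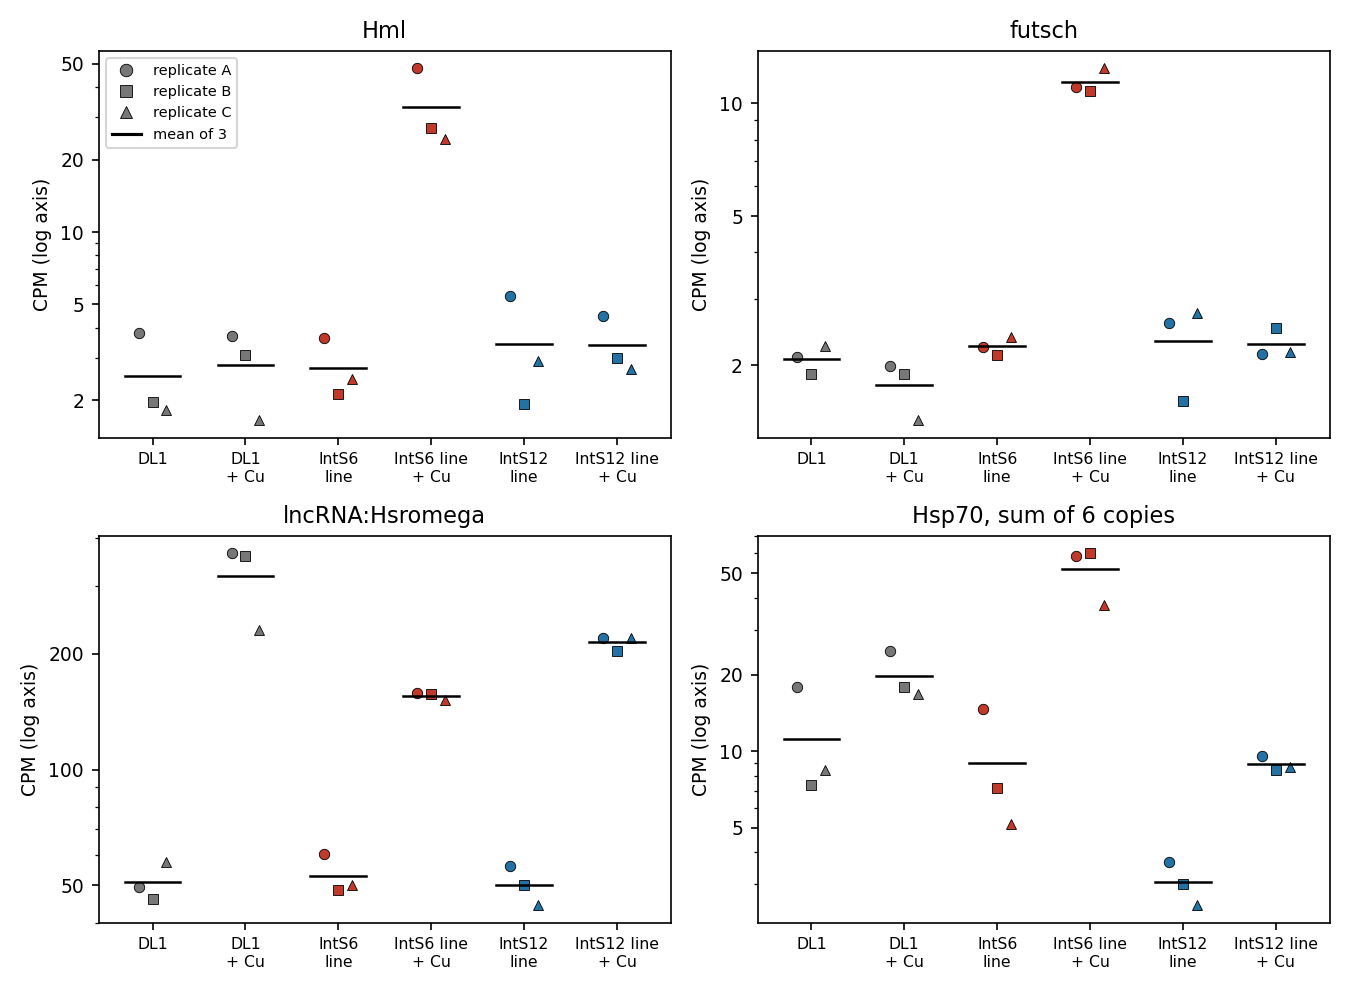
CPM on a log axis of Hml, futsch, lncRNA:Hsromega and the 6 summed Hsp70 copies in each of the 18 libraries, by group, with symbols for the replicate letters and a line at the mean of 3. The summed Hsp70 copies have a mean of 51.9 CPM in the IntS6 line with copper, 19.7 CPM in parental cells with copper and 8.89 CPM in the IntS12 line with copper.

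Genes described earlier as attenuated by Integrator rose with IntS6 in 7 of 8 cases, and in 7 adjusted over the list alone (median log2 0.96, camera adjusted p = 8.88e-09, and adjusted p = 0.0019 with an estimated correlation). This list was set from earlier work and not from these samples, but its members MtnA, MtnB and MtnD also rose with copper alone. Stronger copper exposure of the IntS6 copper libraries was not parted from an effect of IntS6 for these genes. Among its members Pepck1, a gluconeogenic enzyme gene, rose 3.98-fold, MtnA 1.72-fold, the learning gene pst 1.58-fold and kay, the fly Fos gene, 1.48-fold. All exon bases of Pepck1 are shared with CG45087 on the same strand. The transgene plasmids carry the MtnA promoter, and whether they carry transcribed MtnA sequence is not given in the sources used here. Genes of metallothioneins and metal handling rose further than with copper alone in 4 of 12 cases (5 adjusted over the list alone), with MtnB up 2.21-fold, ZnT63C 1.44-fold and ATP7 1.34-fold (camera adjusted p = 0.0147, and adjusted p = 0.242 with an estimated correlation).

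Of 18 heat shock genes 10 were higher and 1, lncRNA:Hsromega, was lower with IntS6 than in copper-treated parental cells (12 and 1 adjusted over the list alone). Near-identical Hsp70 copies are separate members of this list, so such counts can hold the same change more than once. Among them Hsp68 rose 2.14-fold, the co-chaperone gene stv 1.99-fold and Hsp27 1.71-fold, and the 6 Hsp70 copies summed rose 2.64-fold (log2 1.40 ± 0.25, adjusted p = 0.000687). The list had a camera adjusted p = 7.72e-05, and adjusted p = 0.251 with an estimated correlation. Crystal cell and lamellocyte markers rose in 3 of 5 cases (4 adjusted over the list alone), with peb up 4.97-fold, Treh 1.49-fold and cher 1.25-fold (camera adjusted p = 0.00118, and adjusted p = 0.169 with an estimated correlation). Most of their mean log2 of 0.717 came from peb, which is also among the genes described earlier as attenuated by Integrator. Plasmatocyte markers rose in 4 of 13 cases (6 adjusted over the list alone), which besides Hml were Ppn (1.47-fold), glec (1.36-fold) and drpr (1.27-fold), with a camera adjusted p = 0.0134 and adjusted p = 0.311 with an estimated correlation. Most of the mean log2 of 0.411 of these markers came from Hml. Ecdysone response genes rose in 4 of 14 cases (5 adjusted over the list alone), with the nuclear receptor gene Hr4 up 4.59-fold, ImpL2 1.74-fold, E23 1.33-fold and Eip74EF 1.22-fold (camera adjusted p = 0.00172, and adjusted p = 0.0564 with an estimated correlation). ImpL2 shares 61.9% of its exon bases with another gene on the same strand. Some members lost their calls when 1 library was left out. Ppn did so without IntS6 copper library A (adjusted p = 0.0702) or parental copper library C (0.0555), and drpr without parental copper library A (0.0918) or C (0.104) or IntS6 copper library B (0.12). This held for glec without parental copper library B (0.0663) or C (0.0955) or IntS6 copper library A (0.171) or B (0.0724). Eip74EF did so without parental copper library A (0.0649) or C (0.164) or IntS6 copper library A (0.128) or C (0.0817), and cher without parental copper library A (0.103) or C (0.166) or IntS6 copper library A (0.0929), B (0.0627) or C (0.0878). These members except Ppn also lost their calls when only the groups compared were fitted, with adjusted p from 0.0666 for cher to 0.173 for Eip74EF.

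Glycolysis and gluconeogenesis genes rose in 4 of 14 cases (5 adjusted over the list alone), with fbp, the fructose bisphosphatase gene, up 2.84-fold, Hex-A 1.31-fold and Pgi 1.26-fold beside Pepck1 (camera adjusted p = 0.00172, and adjusted p = 0.469 with an estimated correlation). JNK and JAK-STAT targets rose in 5 of 17 cases, and 5 adjusted over the list alone, with Mmp2 up 1.81-fold, Ets21C 1.59-fold and puc 1.3-fold (camera adjusted p = 0.0127, and adjusted p = 0.169 with an estimated correlation). Pgi lost its call without parental copper library A (0.0938) or C (0.204) or IntS6 copper library B (0.189) or C (0.0658) and when only the groups compared were fitted (0.123), and Ets21C without parental copper library A (0.0696) or C (0.0552). Replication-dependent histones (mean log2 -0.15, 0 of 111 called) and ribosomal proteins (mean -0.07, 0 of 82 called) lay lower as sets, with camera adjusted p = 0.000959 and 0.000919, and adjusted p = 0.642 and 0.583 with an estimated correlation. Neither list had a member called adjusted over the list alone. Of 23 spliceosomal and U7 snRNA genes 1 was lower, also adjusted over the list alone, snRNA:U1:21D by 1.33-fold, which was not called without IntS6 copper library A (adjusted p = 0.0683). The snRNA list and that of pausing and elongation factors (0 of 15 called, by either adjustment) both had a camera adjusted p = 0.0409, with adjusted p = 0.583 and 0.169 with an estimated correlation. The pausing call ended with library sizes alone (adjusted p = 0.0713).

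Most lists that did not pass with IntS6 held called genes, where 728 of all 8174 tested genes were called. Integrator subunits (camera adjusted p = 0.475) had 2 of 14 higher, IntS6 and omd (1.26-fold). omd lost its call without parental copper library A (0.0779) or B (0.129) or IntS6 copper library A (0.258) or B (0.0528) and when only the groups compared were fitted (0.137). Oxidative stress genes (0.205) had 4 of 26 higher and 1 lower, with GstE3 up 2.26-fold, and innate immune genes (0.0624) 3 of 16 higher, pirk (2.98-fold), spz (1.75-fold) and Tl (1.61-fold). ATF4 genes (0.0696) had 3 of 16 higher, with CG6287 up 3.17-fold, and passed with the replicate block (0.0462) or library sizes alone (0.0452), and ER unfolded protein response genes (0.0725) had 1 higher and 2 lower of 18, with ERp60 down 1.28-fold. Cell cycle genes (0.0597) had 1 of 32 higher, stg at 1.63-fold, and passed as lower with the replicate block (0.0299). The list of sterol and fatty acid synthesis (0.296) had 2 of 16 members higher, among them the lipase gene bmm, not called without IntS6 copper library A (0.0619) or B (0.0564). Of other cell types, neuron markers (0.41) had 1 of 4 higher, futsch, muscle markers (0.778) 1 of 4, sls at 2.67-fold, and germline markers (0.475) 0 of 4. The PP2A subunits had 0 of 7 called (camera adjusted p = 0.778), with wdb at a log2 fold change of 0.06 ± 0.07. The Integrator, neuron and muscle lists had mean log2 fold changes of 0.41, 0.50 and 0.25 but medians of -0.02, -0.07 and -0.09, and were ranked up by camera. Of the 23 lists tested here 1, the genes described earlier as attenuated by Integrator, passed with an estimated correlation.

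**Figure D3:**
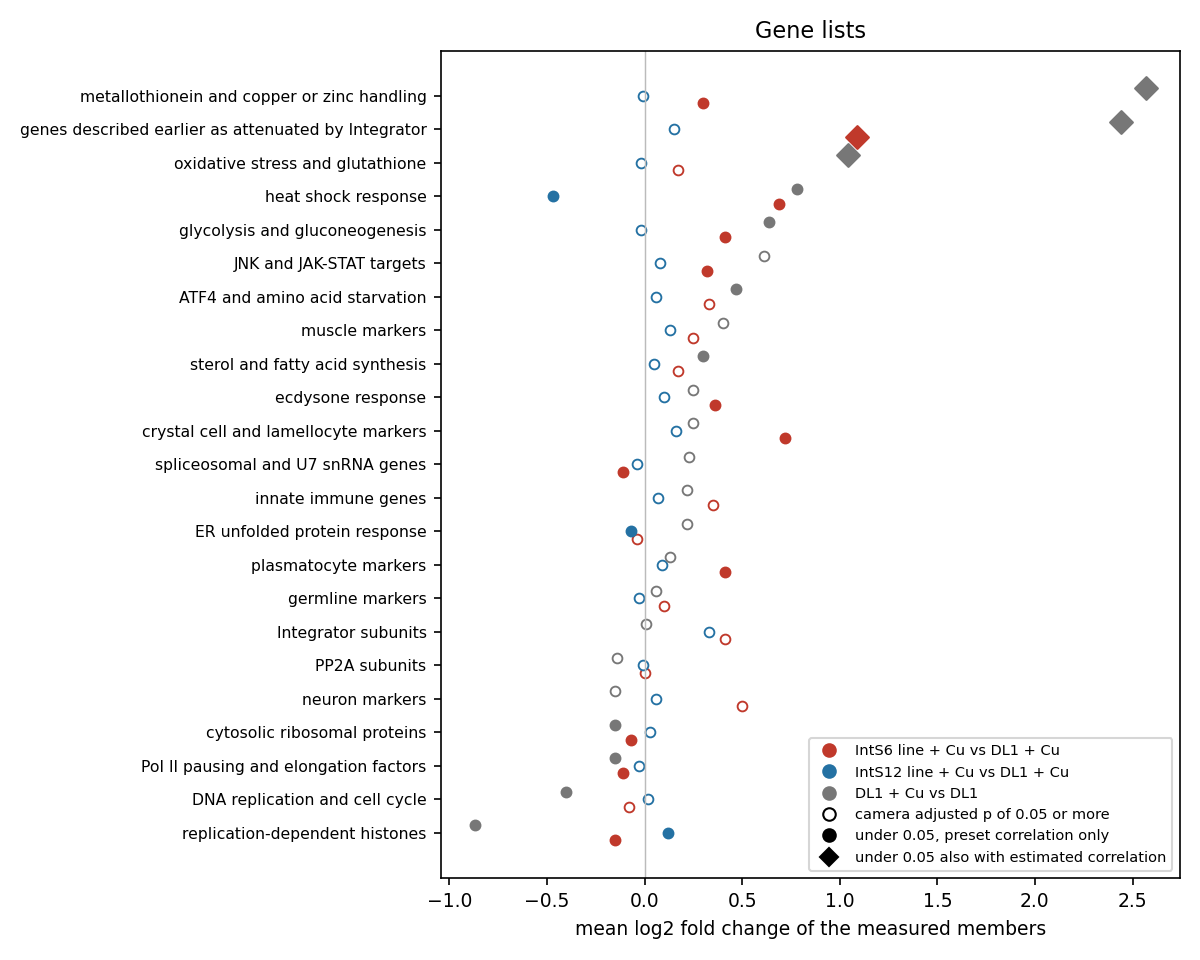
Mean log2 fold change of the measured members of each of 23 gene lists (horizontal axis) for IntS6 line with copper (red) and IntS12 line with copper (blue) against parental cells with copper, and for copper in parental cells (grey). Filled symbols passed camera with the preset correlation and diamonds passed with an estimated correlation too, as genes described earlier as attenuated by Integrator did with IntS6 (adjusted p = 0.0019).

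With IntS12 overexpressed, against parental cells given the same copper, 2 genes changed. IntS12 itself rose 25.6-fold. Tmtc2, which lies outside the rule for named genes and was chosen after its values were seen, was lower at 0.529 ± 0.194 CPM against 2.64 ± 0.565 CPM (SD, n = 3, log2 -2.30, adjusted p = 0.00364). Tmtc2 was also lower in this line without copper (log2 -2.31, adjusted p = 0.00134) and in the IntS6 line with copper (log2 -3.16, adjusted p = 7.31e-06). At an unadjusted p under 0.05 there were 297 genes, and DESeq2 called 5. The count was 7 without parental copper library C, and 1 without parental copper library A or IntS12 copper library A or B.

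Heat shock genes had a mean log2 fold change of -0.47 with IntS12 against copper-treated parental cells, with 0 of 18 called over all genes and 7 lower adjusted over the list alone. Without copper their mean in this line against parental cells was already -0.53, so the difference was present before induction. lncRNA:Hsromega stood at -0.57 ± 0.12 (adjusted p = 0.215), Hsp70Bbb at -1.15 ± 0.27 (0.293) and Hsp23 at -0.86 ± 0.22 (0.458). The list's camera adjusted p was 4.25e-09, and adjusted p = 0.379 with an estimated correlation. The ER unfolded protein response list (mean log2 -0.07) and the histones (mean 0.12), with 0 members called by either adjustment, had camera adjusted p = 0.00094 and 0.00428, and adjusted p = 0.379 and 0.962 with an estimated correlation. The genes described earlier as attenuated by Integrator had 0 of 8 called (mean log2 0.15, camera adjusted p = 0.511), with MtnA at 0.28 ± 0.13, pst at 0.14 ± 0.10 and kay at 0.13 ± 0.09. The 20 lists that did not pass, this list among them, had camera adjusted p from 0.427 to 0.992.

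Set directly against each other with copper present, the IntS6 and IntS12 lines differed in 474 genes, 414 higher and 60 lower in the IntS6 line. The count fell to 307 without IntS12 copper library A, 309 without IntS12 copper library C and 315 without IntS6 copper library C, with 26 to 41 lower in the fits without 1 library. With library sizes alone 375 were higher and 29 lower, and without a filter on low counts 557 and 113. With the replicate block 92 were lower. Apart from the transgenes, Hml was 9.76-fold higher with IntS6 (log2 3.29 ± 0.30, adjusted p = 2.62e-07) and Hsp70Aa 7.04-fold (2.82 ± 0.32), with the summed Hsp70 copies 5.83-fold higher (51.9 against 8.89 CPM, adjusted p = 3e-06). Without copper the summed copies already stood at 9.01 CPM in the IntS6 line against 3.06 CPM in the IntS12 line. CG9752 (1.71-fold) and CG30283 (1.68-fold) were lower with IntS6. CG9752 lost its call without IntS12 copper library A or B (adjusted p = 0.168 and 0.109) or IntS6 copper library B or C (0.156 and 0.136) and with library sizes alone (0.0613). CG30283 lost it without IntS6 copper library B (0.1) or IntS12 copper library B or C (0.117 and 0.0562). Genes attenuated by Integrator were higher with IntS6 in 6 of 8 cases, and 8 adjusted over the list alone (camera adjusted p = 2.62e-09, and adjusted p = 0.00185 with an estimated correlation), with Pepck1 4.46-fold and MtnB 2.31-fold higher. Heat shock genes were higher in 12 of 18 cases and lower in 1 (13 and 1 adjusted over the list alone), with Hsp23 4.21-fold higher (camera adjusted p = 2.29e-12, and adjusted p = 0.0578 with an estimated correlation). Ecdysone response genes also passed with either correlation (camera adjusted p = 0.000887, and adjusted p = 0.0381 with an estimated correlation), with 1 of 14 called, Hr4 at 2.45-fold, also adjusted over the list alone. Histones (mean log2 -0.26) and ribosomal proteins (mean -0.10) lay lower as sets with IntS6 (camera adjusted p = 2.62e-09 and 1.05e-05, and adjusted p = 0.509 for both with an estimated correlation), as did cell cycle genes (mean -0.09, 1 higher and 1 lower of 32, and 1 and 2 adjusted over the list alone, camera adjusted p = 0.0379, and adjusted p = 0.682 with an estimated correlation). Induced IntS6 stood at 2370 CPM and induced IntS12 at 92.9 CPM, values not scaled for gene length. Their rises over copper-treated parental cells were 65.1-fold and 25.6-fold, so the lines cannot be taken as matched for transgene level.

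Across the 8174 genes, which are not independent replicates, the log2 fold changes of the IntS6 and IntS12 lines against the shared parental copper libraries had a Pearson r of 0.45 and a Spearman rho of 0.41. Simulated unchanged groups gave a Pearson r of 0.50 on average, with no effect of the replicate letters, which may pair the IntS6 and parental copper libraries. The covariance was 0.0487 against 0.0225 in the simulations, a difference of 0.0262. Shared controls add the variance of their mean to the covariance, and for the 3 real control libraries that variance was 0.0429. Most of the covariance may thus come from the shared controls, which are too few to tell whether the rest is a shared effect. The covariance was 0.0769 without parental copper library A and 0.0956 without parental copper library B. The 1 gene called higher in the IntS12 line was IntS12 itself, and 0 were shared with IntS6 (0.0745 by independent lists). Of those called lower 1, Tmtc2, was shared (0.0146 by independent lists). Simulated unchanged groups gave 0 in each direction, and independent lists leave out the shared controls. Without parental copper library C 4 of 5 higher and 2 of 2 lower calls were shared, and with the replicate block 2 of 3 higher and 1 of 3 lower, with no simulation run for these fits.

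**Figure D4:**
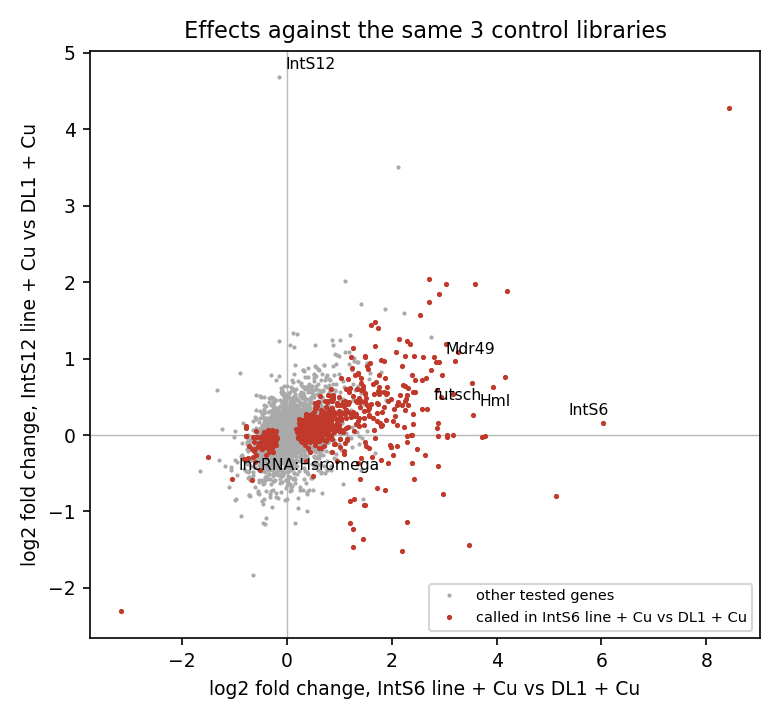
Log2 fold changes of 8174 genes in the IntS6 line (horizontal axis) and the IntS12 line (vertical axis), both with copper, against the same 3 parental copper libraries, with genes called for IntS6 in red. Across genes r is 0.45, against 0.50 in simulated unchanged groups.

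Without copper the transgene lines lay close to parental cells. In the IntS6 line ds was 5.58-fold higher (log2 2.48 ± 0.29, adjusted p = 4.77e-05), LamC, which encodes an A-type lamin, 2.04-fold higher (1.03 ± 0.12) and CG31601 1.86-fold lower (-0.90 ± 0.13). In all 15 genes, IntS6 among them, were higher and 2 lower, and none of the 23 lists passed camera (adjusted p from 0.0946 to 0.981), though the histones did so with library sizes alone (0.0103). In the IntS12 line 3 genes differed: ds was 3.42-fold higher (1.77 ± 0.31, adjusted p = 0.033), IntS12 was higher and Tmtc2 was lower. There were 213 genes at an unadjusted p under 0.05, DESeq2 called 8, and the count was 1 without parental library A or IntS12 library B or C. The call of ds in the IntS12 line ended when only the groups compared were fitted (adjusted p = 0.153) and without parental library A (0.217) or B (0.133) or IntS12 library B (0.303) or C (0.217). The Integrator list, with IntS12 as its 1 called member by either adjustment, had a camera adjusted p = 0.0322, and adjusted p = 0.276 with an estimated correlation. Heat shock genes in the IntS12 line had a mean log2 fold change of -0.53 with 0 of 18 called and 4 lower adjusted over the list alone (camera adjusted p = 5.49e-07, and adjusted p = 0.383 with an estimated correlation). The summed Hsp70 copies stood at 3.06 ± 0.599 CPM there against 11.2 ± 5.76 CPM in parental cells (log2 -1.86 ± 0.37, adjusted p = 0.0677).

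Copper changed 3479 genes in the IntS6 line (1900 higher, 1579 lower) and 3007 in the IntS12 line (1570 higher, 1437 lower). In the IntS6 line MtnD was at least 324-fold and MtnB at least 163-fold higher and MtnA 181-fold, while CG9752 fell 3.79-fold, Ids, the iduronate sulfatase gene, 3.3-fold and His1:CG33819 3.17-fold. In the IntS12 line MtnB was at least 74.9-fold higher, MtnD had a ratio of counts of 399 (interval 110 to 3300, from 2 counts without copper, with a fitted log2 of 8.38 that was 7.78 without IntS12 library A), MtnE rose 172-fold and MtnA 128-fold. Among the falls CG6675 fell 4.2-fold, Muc14A 3.55-fold and nw 3.36-fold. Histones fell in 111 of 111 cases in the IntS6 line and 104 of 111 in the IntS12 line, and adjusted over the list alone in 111 and 107 (camera adjusted p = 2.48e-22 and 4.9e-20, and adjusted p = 0.285 and 0.377 with an estimated correlation). Genes attenuated by Integrator, metallothioneins and oxidative stress genes passed with an estimated correlation in either line (adjusted p = 0.0052, 0.0136 and 0.0266 in the IntS6 line and 0.0128, 0.0128 and 0.0329 in the IntS12 line). So did pausing and elongation factors in the IntS6 line, which fell in 8 of 15 cases, also adjusted over the list alone (camera adjusted p = 0.00114, and adjusted p = 0.0224 with an estimated correlation).

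The copper response of each line was tested against that of parental cells. For the IntS6 line 95 genes differed, 92 with a more positive and 3 with a more negative response. It was 151 with the replicate block, 238 without a filter on low counts and 62 when only the groups compared were fitted. Hml (log2 difference 3.46 ± 0.55, adjusted p = 0.00115) and Gs2 (3.03 ± 0.50) led the former besides IntS6 itself. The latter were lncRNA:Hsromega (-1.09 ± 0.18, adjusted p = 0.00194), CROT (-0.93 ± 0.20) and CG8726 (-0.57 ± 0.14, adjusted p = 0.0496). CROT lost its call without parental library A (adjusted p = 0.0748), IntS6 copper library A (0.0602) or IntS6 library C (0.0632). CG8726, which overlaps nito on the other strand over 12.7% of its exon bases, lost it with DESeq2 (0.0562), under 4 other settings (0.0511 to 0.097). It also lost it without any 1 of the 12 libraries compared except parental copper library C and IntS6 copper library C (0.0578 to 0.154). The count fell to 43 without parental library A, to 46 without IntS6 library C and to 48 without IntS6 copper library A or IntS6 library B. For the IntS12 line 1 gene differed, IntS12 itself (log2 difference 3.93 ± 0.19, adjusted p = 6.1e-12), with 174 genes at an unadjusted p under 0.05 and 1 called by DESeq2.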

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

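The comparison with the IntS12 line as a test of stable transgene lines, the alternative without rRNA genes and the second way of regrouping libraries for the copper responses were tests chosen only after the results were seen. Counts of called genes from a first fit were known before the outcomes of the other tests were written down.

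A test of the difference between copper responses set apart 95 genes for the IntS6 line against parental cells and 1 gene for the IntS12 line, IntS12 itself (log2 difference 3.93). The direct contrast of the copper-treated lines set apart 474 genes. For the IntS6 line the largest log2 differences among genes named here were those of IntS6 (4.67), Hml (3.46), Gs2 (3.03), Mdr49 (3.00) and futsch (2.56). Hsp70Aa (1.95), Hsp68 (1.32), the co-chaperone gene stv (0.88), Hsp27 (0.75), the zinc transporter gene ZnT63C (0.69), pst (0.69) and stg (0.61) also passed with a more positive response. lncRNA:Hsromega (-1.09), CROT (-0.93) and CG8726 (-0.57) passed with a more negative one.

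The same test over gene lists brought up 11 of 23 for the IntS6 line. Genes described earlier as attenuated by Integrator had a mean log2 difference of 0.98, with 1 of 8 called and 4 adjusted over the list alone (camera adjusted p = 4.32e-08, and adjusted p = 0.00275 with an estimated correlation). The other 10 lists did not pass with an estimated correlation, where their adjusted p ran from 0.209 to 0.735. Of these, heat shock genes had a mean difference of 0.82 with 6 of 18 higher and 1 lower (10 and 1 adjusted over the list alone). The mean differences of the rest were crystal cell markers 0.63, glycolysis 0.48, plasmatocyte markers 0.42, ATF4 genes 0.36, JNK targets 0.28, ecdysone response genes 0.28, metallothioneins 0.24, ribosomal proteins -0.07 and pausing factors -0.10. Hml, at a log2 difference of 3.46, added most of the plasmatocyte mean. The pausing list missed the threshold with the replicate block (adjusted p = 0.0532) or library sizes alone (0.072), and the ecdysone list with the replicate block (0.0523). For the IntS12 line 0 of 23 lists passed camera (adjusted p from 0.126 to 0.918 over both correlations).

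Regrouping the 12 libraries of each copper response test gave results as large in 10 of 100 splits for the IntS6 line (highest other 2784 against the real 95) and in 14 of 100 for the IntS12 line (highest other 2413 against 1). With line labels regrouped within each copper level it was 9 of 100 (highest other 323) and 17 of 100 (highest other 114). Counts many times the real ones point to a structure of the samples: in the first way copper labels were regrouped within each line, and the splits with the highest counts kept those of one line as labelled and mixed those of the other. In the second way all 8 other splits with as many calls for the IntS6 line, and 10 of 16 for the IntS12 line, kept the copper libraries as labelled, and 10 such splits were drawn for each line. The splits that mixed the copper libraries of the IntS6 and parental lines gave at most 2 calls. Because most splits with as many calls kept part of the real copper or line differences, these shares decide nothing on chance for either count.

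For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. As many calls came in 1 of 10 splits, the real one, for IntS6 with copper against parental cells with copper (728, highest other 25), for copper in parental cells (3159, highest other 0). The same held for copper in the IntS6 line (3479, highest other 0) and in the IntS12 line (3007, highest other 1). It also held for the IntS6 line (17, highest other 0) and the IntS12 line (3, highest other 1) without copper, and for the 2 induced lines against each other (474, highest other 0). In the first of these the replicate letters may pair the samples, with same-letter r of 0.21, 0.24 and 0.13. The 3 other splits that part every pair gave 0 calls. For IntS12 with copper against parental cells with copper it was 2 of 10. A split with parental copper libraries A and C and IntS12 copper library A on one side gave 47 calls against the real 2, which points to a structure of the samples that does not follow the letters. With the replicate block the count there was 6.

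More genes were higher than lower with IntS6 induced, 609 against 119. A general effect of a stable line given copper, as the whole cause, is argued against by the IntS12 line, whose calls came to 0.275% of those of the IntS6 line, but 79.5% of the 609 genes lay above 0 there (median log2 0.13 against 0.74, with shared controls and no value for unchanged genes), so a part stays open. Stronger copper exposure, as the whole cause, is argued against by the IntS6 line set against the IntS12 line, both with copper. The slope of that contrast on the parental copper effect was -0.217 times as large for copper-lower as for copper-higher genes (-0.465 to 0.036 without 1 library). The test takes falls to deepen in proportion to rises, and it did not use the contrast that gave 609 and 119 genes. But the slope of copper-higher genes was 0.164, and histones, ribosomal proteins and cell cycle genes lay lower than in the IntS12 line. MtnA (549 against 387 CPM) and MtnB (11 against 4.77 CPM) stood higher than in the IntS12 line with copper, as did MtnD and MtnE. On the first component IntS6 copper libraries lay at 36 to 40.5 against 16.6 to 29.8 for the other copper libraries, so a part stays open. A gene length trend, as the whole cause, is argued against by the 86.7% of higher calls kept after its removal (571 higher and 144 lower after it), but length and fold change had a Spearman rho of 0.24 and the median exon length was 4014 bases for higher genes against 2043 for all, so a part stays open, and scaling between libraries is argued against by a share of higher calls of at least 80.9% under the 3 other scalings run, which leave a global change in RNA per cell open because no spike-in counts were used. A drift of the IntS6 line that is alike with and without copper, as the whole cause, is argued against by values without copper. Genes higher with induction, IntS6 left out, had a median log2 of 0.04 there between the IntS6 and IntS12 lines. It was 0.74 for IntS6 against parental cells, both with copper, and a part stays open. An effect of excess IntS6, the amount of transgene product, which was not measured, and a drift in the line's response to copper stay open. No test here parted them.

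In the IntS6 line without copper the IntS6 transcript was 2.55-fold higher than in parental cells and 17 genes were called, and its effect may lean toward that of induction. Across the 727 genes called with IntS6 induced, transgenes left out, the log2 fold changes of IntS6 against IntS12 lines without copper had r = 0.144 with those of induction, and a Spearman rho of 0.173. The medians were 0.04 for genes higher and -0.03 for genes lower with induction, and 5 genes were called between those lines. An r of 0.3 had been set for leaky expression and one under 0.1 against it, and the value lies between. A drift of the IntS6 line enters both contrasts and raises r as leaky expression does. No value of r could therefore tell leaky expression and a drift of the line apart for these genes.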

How the results depend on the processing

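Leaving out the rRNA genes was an alternative chosen after the data were seen. Of the 189 called values of named genes, 41 lost the call under some alternative, in 161 of 2686 fits of which 121 left out 1 library, and none reversed. For the changes below the cause was not tested, except that a stricter threshold makes fewer calls by construction. IntS12 had 45 to 84 counts per library in parental cells, and no test was made of what depth limits.

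With an adjusted p under 0.001 and a fold over 1.5 the counts were 169 for IntS6 and 1 for IntS12 against parental cells, all with copper, and 883 for copper in parental cells. They were 1220 in the IntS6 line and 815 in the IntS12 line for copper, 7 and 0 for the IntS6 and IntS12 lines without copper, 97 between the induced lines and 16 for the copper response of the IntS6 line against parental cells. Beside that 0, edgeR had 213 genes at an unadjusted p under 0.05 and DESeq2 called 8. With only the groups compared fitted, the counts were 454 (443 of them among the 728), 1 for IntS12 with copper, 1 for IntS12 without copper and 62 for the IntS6 response difference. There the log2 fold change of IntS12 was -0.45 for copper in parental cells (adjusted p = 0.0596, over alternatives up to 0.0929) and 0.75 in its own line without copper (adjusted p = 0.23, over alternatives up to 0.303). Without a filter on low counts 22 genes were called for IntS12 with copper, 48 and 32 for the IntS6 and IntS12 lines without copper, and 238 and 8 for the response differences of the IntS6 and IntS12 lines. DESeq2 called 5 genes for IntS12 with copper and 8 without, and 5 were called without copper when rRNA genes were left out.

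With the replicate block 893 genes were called for IntS6 with copper, 727 of them among the 728, and 3323 for copper in parental cells, the 2 comparisons whose letters may pair the samples. In these the block ended the call of the sterol list for copper and added those of the ATF4 and cell cycle lists for IntS6, and changed no other call of a named gene or list. Over all groups, these comparisons included, 15 of 45 same-letter pairs correlated above 0.1. Where the letters are only shared, the block gave 6 genes for IntS12 with copper and 6 without. For the IntS6 response difference, which holds the groups of both comparisons that may be paired, it gave 151. Between the induced lines, where same-letter r was 0.09, -0.04 and 0.02, it gave 616 against 474. A rise in calls with the block therefore does not show pairing.

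With an estimated correlation 1 gene list passed for IntS6 with copper, 0 for IntS12 with copper, 3, 4 and 3 for copper in parental cells, the IntS6 line and the IntS12 line. It was 0 for the IntS12 line without copper, 2 between the induced lines and 1 for the IntS6 response difference. With fry the numbers were 1 for IntS12 with copper, 17 and 17 for copper in parental cells and in the IntS12 line, 1 for the IntS6 line and 0 for the IntS12 line without copper. That 1 for IntS12 with copper was the Integrator list, which holds IntS12 (fry adjusted p = 0.00019). The heat shock (0.298), ER (0.396) and histone (0.915) lists lost their calls there. For IntS6 with copper the histone (0.521), ribosomal protein (0.32) and snRNA (0.296) lists lost theirs, and the Integrator, ATF4, innate immune and neuron lists gained one. With library sizes alone 1 list passed for the IntS6 line without copper. The correlation of the IntS6 and IntS12 effects was 0.843 when each line with copper was set against its own line without, which puts the copper effect into both by construction.

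Leaving out 1 library at a time gave 521 to 812 calls for IntS6 with copper, 76% to 87.9% of them higher. For IntS12 with copper it gave 1 (without parental copper library A or IntS12 copper library A or B) to 7 (without parental copper library C), and for the IntS12 line without copper 1 (without parental library A or IntS12 library B or C) to 3. Between the induced lines it gave 307 to 395, lowest without IntS12 copper library A (307) or C (309) or IntS6 copper library C (315). For the IntS6 response difference it gave 43 (without parental library A) to 99, with 46 to 48 without IntS6 library B or C or IntS6 copper library A. The log2 fold change of IntS12 ran from -0.304 to 0.007 for IntS6 with copper, turning positive without IntS6 copper library A, and from -0.531 to -0.383 for copper in parental cells. It ran from 0.643 to 0.866 for its own line without copper and from -0.064 to 0.247 for the IntS6 response difference, turning negative without IntS6 copper library B. That of IntS6 in the IntS12 response difference ran from -0.054 to 0.064, turning positive without IntS12 copper library B. The correlation of the IntS6 and IntS12 effects ran from 0.347 (without IntS12 copper library B) to 0.583 (without parental copper library B).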

Other observations

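The comparison of the shared covariance with the variance of the control libraries was the 1 test here chosen only after the result was seen. Copper changed members of further gene groups in parental cells whose lists did not pass as a set. Over all genes it changed 3159 of 8174, a share that the innate immune and snRNA lists did not exceed. Of 18 ER unfolded protein response genes 9 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.0681), with the ER chaperone gene Gp93 up 1.99-fold and PEK, an ER stress kinase gene, up 2.15-fold. The stress sensor gene Atf6 fell 1.89-fold. Of 16 innate immune genes 3 rose and 2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.326), with Sting up 1.9-fold, PGRP-LF 1.83-fold and spz 1.82-fold. PGRP-LF overlaps UGP on the other strand over 44.4% of its exon bases, and whether the counting used strand is not given. Ecdysone response genes rose in 5 and fell in 4 of 14 cases, as they did adjusted over the list alone (camera adjusted p = 0.752), with Hr4 at 28 against 2 counts (a ratio of 13.9, 95% interval 3.49 to 120) and usp, the RXR homolog gene, down 1.3-fold. Spliceosomal and U7 snRNA genes rose in 7 and fell in 1 of 23 cases, also adjusted over the list alone (camera adjusted p = 0.0725), with snRNA:U4:38AB up 1.81-fold, and copies of these genes are near-identical and their counts uncertain.

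Hemocyte markers moved both ways with copper. Plasmatocyte markers rose in 5 and fell in 4 of 13 cases, also adjusted over the list alone (camera adjusted p = 0.909, ranked down though the mean log2 was 0.13 and the median 0.15). The phagocytic receptor gene eater fell 1.86-fold and the GATA factor gene srp 1.39-fold, while the scavenger receptor gene crq rose 1.72-fold. Overlaps with another gene covered 15.7% of the exon bases of crq on the other strand and 16.1% of those of srp on the same strand. Among germline markers, with 1 higher and 2 lower of 4 (1 and 3 adjusted over the list alone, camera adjusted p = 0.534, mean log2 0.06 and median -0.31), the Piwi-family genes parted: piwi rose 3.69-fold and aub fell 2-fold.

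Both stable lines differed from parental cells in Tmtc2 and ds without copper. Tmtc2, outside the rule for named genes and chosen after its values were seen, stood at 3.63 ± 0.663 CPM in parental cells without copper against 0.159 ± 0.0748 CPM in the IntS6 line and 0.723 ± 0.0821 CPM in the IntS12 line (SD, n = 3). The cadherin gene ds stood at 2.13 CPM in parental cells against 11.8 and 7.30 CPM in those lines without copper. With copper it stood at 0.957 CPM against 5.98 and 3.77 CPM, where the log2 fold change in the IntS12 line was 2.04 and not past the threshold (adjusted p = 0.072).

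Across the 5564 genes with a mean of at least 5 CPM, the effects of IntS6 and IntS12 against shared controls had r = 0.37 and a covariance of 0.0119, against 0.51 and 0.00789 in simulated unchanged groups. The difference in covariance was 0.00404. The whole covariance was no larger than the variance of the mean of the 3 control libraries, 0.0122, which shared controls add to it.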
